A study of Drosophila melanogaster with 2 samples.

How the data were processed

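Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 2 biological replicates of transgenic Drosophila melanogaster embryos that carried CG17328 fused to enhanced green fluorescent protein. Per the labels, embryos of 0 to 24 h were used whole, chromatin was sheared by sonication, and an antibody against the fluorescent protein pulled down the fusion. Both samples formed 1 group, with the replicate numbers given in the labels. No second group and no control library was analysed here.

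The deposited files were peak lists on the dm6 assembly, per the file headers and listings. Each sample had its own ranked list and its own thresholded list. The series had 2 ranked and 2 thresholded lists derived from the alignments of both samples, one of them called conservative by the authors. The aligner, the peak caller and their versions are not given in the sources used here. The listings name a control alignment as a further input of the ranked lists. Each deposited list gave a score, which follows the irreproducible discovery rate (IDR, the expected share of peaks that would not recur between the compared sets). The signal column held the authors' peak height, and the −log10 columns the authors' transformed q-values or IDR values. Every deposited peak score in the thresholded lists was at least 830, and every thresholded peak was found in its ranked list at an IDR of 0.01 or less. The peak signal was used to describe, rank or filter peaks within a list, to set shared peaks of the replicates side by side, and as a median over candidates near a place. Whether the signal of both replicates is on 1 scale is not given in the sources used here. Series-level values are the authors' pooled values, without an error of their own. Read depth is unknown, because the lists carry no read counts.

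Coordinates were compared with the reference before use. No peak ended past the end of its chromosome in any list. Gene models came from Ensembl release 115 on assembly BDGP6, with 18277 genes and 24111 start sites on 7 chromosome arms after transposable elements had been left out. The sequence was the soft-masked RefSeq copy of the same assembly. The 5 conservative peaks on unplaced scaffolds were left out of location and sequence tests.

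The background for enrichments was 127960 candidate summits, from the series-level ranked lists, that overlapped no thresholded peak. Among them were 134 peaks at or under the IDR threshold that the thresholded lists leave out. A promoter peak had its summit within 500 bp of an annotated start site. Each summit outside promoters was placed in the first class that applied among 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic sequence. Two-sided Fisher's exact tests compared shares, with Benjamini-Hochberg adjustment within each family and Wilson 95% intervals. These intervals and p-values are over peaks or genes, which are not replicates, and cover counting error only. Overlap between replicates was tested one-sided against 1000 random placements of the replicate 2 peaks on the same chromosomes. Signal agreement was described by Spearman's rho across shared peaks, with 200 bootstrap draws.

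There were 26 gene lists and 28 consensus words, and 6 gene classes of the annotation were tested with the lists as 1 family of 32. Words were counted within 50 bp of the summit and compared, by an exact sign test, with a window of equal length centred 300 bp to a randomly drawn side. Words of 8 letters were ranked on 2L, 2R and 4 and tested on 3L, 3R and X. The genes named are those nearest to the 25 conservative peaks of highest signal that overlapped a thresholded peak of each sample, the tagged gene, and up to 4 members of each list with the highest promoter peaks. The lists, words, tests and this rule were chosen before the data were examined. An early calculation on the data departed from them in the candidate rule, in 1 further gene list and in the number of placements of 1 alternative, and the values given here follow the choices as first made. The G+C content around summits, the side of the start site on which promoter summits lay and the word shares by location were examined only after the data had been seen. A few list symbols were replaced by their current names.

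Alternatives were the other series-level list, the 2901 strongest conservative peaks, each sample's own list, promoter windows of 250 and 1000 bp, word windows of 25 and 100 bp, other overlap rules and other backgrounds. The listed IDR of 0.01 was already the authors' threshold, so the 2901 strongest peaks stood in for a stricter one. Further backgrounds were chosen after seeing the data: candidate summits matched on G+C content with 5 per peak for the fixed words and for the 8-letter word, protein-coding genes only for the lists, and the 12796 strongest candidates for the promoter share. The chromosome shares were also computed, by a choice made after seeing the data, with the left-out peaks past the threshold counted as peaks, as was the number of peaks within 20000 bp of the tagged gene.

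The tests were checked on simulated data. In the gene-list test, run on 18277 genes, 18 of 20 planted lists and 0 of 180 others were called. The word test called 0 of 28 words at 4000 random positions, and the planted 8-letter word ranked 1. Random positions differ from their flanks by 0.0165 points of G+C, against -7.71 points at conservative summits. This check therefore could not show whether such a dip alone leads to word calls. Among 20 random lists of 3000 peaks, 1 had an annotation class called. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and blastn 2.17.0.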

Results

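CG17328 is a zinc-finger protein gene of the fruit fly, and its sites in the embryo were mapped through a fluorescent tag in 2 biological replicates. The conservative list of the authors held 5807 peaks. Replicate 1 had 3713 peaks in its own thresholded list and replicate 2 had 4216. Peaks in the conservative list had a median width of 316 bp. The number of reads behind the lists is unknown, so the replicate lists cannot be set against their depth.

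The first question was whether the peaks of the replicates lay at the same sites. At the start site of CG14100 the signal was 882 in replicate 1 and 1055 in replicate 2, and at Ugalt, a UDP-galactose transporter gene, it was 832 and 1115. Of 3708 replicate 1 peaks on the chromosome arms, 2900 (78.2%, Wilson 95% interval 76.9 to 79.5%) overlapped a replicate 2 peak by at least 1 bp. Of the 4216 replicate 2 peaks, 2899 (68.8%) overlapped one of replicate 1. Random placement gave a mean of 61.7 overlaps and a maximum of 84 (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Across the 2900 shared peaks, Spearman's rho of the signal was 0.819 (bootstrap interval 0.805 to 0.837). This correlation is across peaks, which are not independent replicates. Of the 5802 conservative peaks on the arms, 2891 overlapped a thresholded peak in both samples, 558 in replicate 1 alone, 908 in replicate 2 alone and 1445 in neither.

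**Figure D1:**
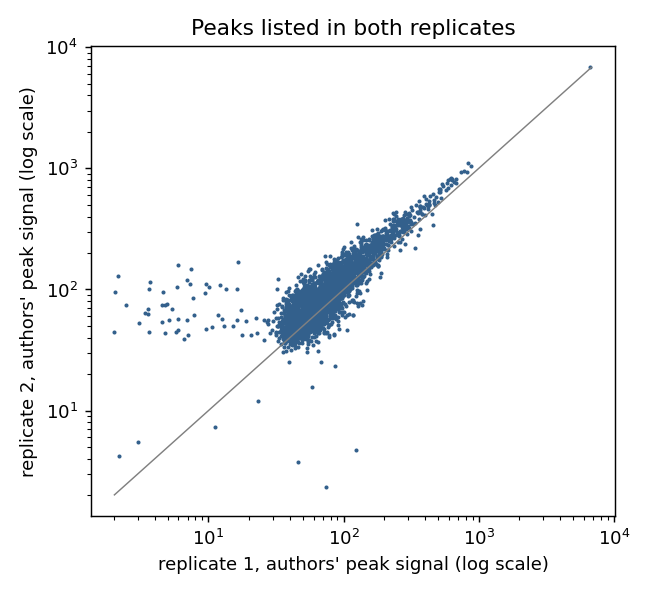
Authors' peak signal in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) for the 2900 peaks of replicate 1 that overlapped a replicate 2 peak; each point is 1 peak and the grey line marks equal values. Most points rise together, with a rho of 0.819, the highest lies at 6636 and 6823, 49 points are over 3 times as high in replicate 2 and 5 over 3 times as high in replicate 1.

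The sites of highest signal were next described by their neighbouring genes. The strongest peak lay on 2R from 22677970 to 22678748 (dm6), in intergenic sequence at -4712 bp relative to the nearest start site, that of lncRNA:CR44761 (FBgn0265982). Its pooled signal was 13769, which was 7.12 times that of the next peak, and it measured 6636 in replicate 1 and 6823 in replicate 2. Among the 25 named peaks, 19 were at promoters, 3 were intronic and 3 were intergenic, and 22 had a protein-coding gene as the nearest one. The second peak was at CG14100 (FBgn0036889, 3L from 19590467 to 19590780, summit at -91 bp relative to the start site), with a pooled signal of 1935. Ugalt (FBgn0024994, X from 2703715 to 2704042) followed at 1934, with its summit at -37 bp.

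Other promoters followed at lower signals. The promoter of ph-p, a Polycomb group gene (FBgn0004861, X from 2137208 to 2137515), had a pooled signal of 1708. At Chro, which encodes the chromodomain protein Chromator (FBgn0044324, 3L from 22878745 to 22879043), it was 1384. The mitochondrial ribosomal protein genes mRpL41 (2R from 15217610 to 15217896) and mRpS10 (3R from 15229391 to 15229677) had 1448 and 1433, and PNPase, the mitochondrial polynucleotide phosphorylase gene, had 1419. The vein-patterning gene px had 1741 and the casein kinase gene gish 1330. Promoter peaks with signals between 1164 and 1496 also lay at CG18549, CenG1A, Tcs5, lncRNA:CR44339, CG5611, lncRNA:CR31044, Fkbp14, CG1888, CG9147 and RluA-1. Outside promoters, intronic peaks nearest to the start sites of CG11050, HmgZ and Tlk had 1692, 1189 and 1159. Intergenic peaks nearest to CG13323 and CG31668 had 1426 and 1149.

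Promoters held far more of the conservative peaks than of the candidates. Of 5802 conservative summits, 2499 (43.1%, interval 41.8 to 44.3%) lay within 500 bp of a start site, against 15.3% of 127960 candidate summits (odds ratio 4.19, Fisher's exact test, −log10 p = 523). Against the 12796 strongest candidates, a background chosen after seeing the data, of which 25.2% lay at promoters, the odds ratio was 2.25. Promoter summits sat on the upstream side in 1810 of 2499 cases (72.4%), with a median position of -83 bp relative to the start site. The upstream share has no background beside it, so it only describes these summits. Coding exons were nearly empty of peaks, with 72 summits (1.24%) against 21.7% of candidates (odds ratio 0.0454). The 3′ UTRs held 0.982% against 2.86%, and intergenic sequence 16.5% against 21.5% (exact adjusted p = 7.8e-22 and 1.51e-20). Introns held 36.8% of conservative and 36.7% of candidate summits (exact adjusted p = 0.813). The promoter share was 46.5% in the own list of replicate 1 and 43.7% in that of replicate 2. Coding exons held 0.701% and 0.451% of summits in those lists (odds ratios 0.0255 and 0.0163).

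**Figure D2:**
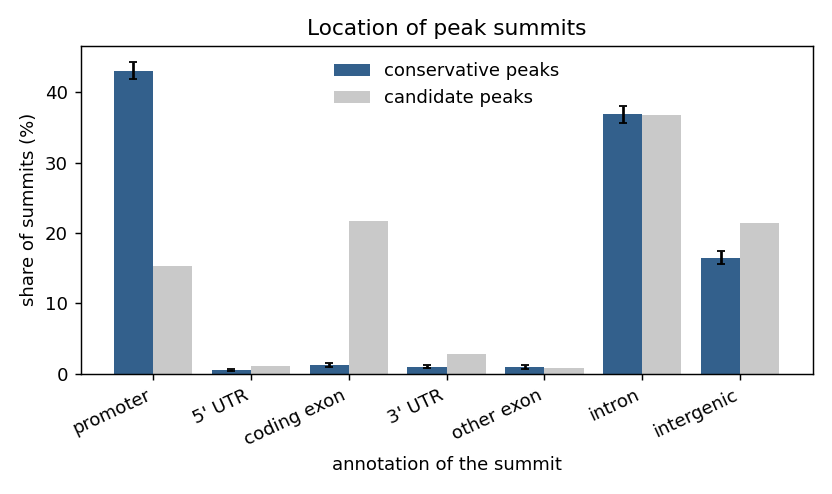
Share of summits in percent (y axis, from 0) by annotation class (x axis) for 5802 conservative peaks, with Wilson 95% intervals as error bars, and 127960 candidate peaks. Promoters hold 43.1% of conservative and 15.3% of candidate summits, and coding exons 1.24% and 21.7%.

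The large chromosome arms differed little in their shares. Arm 2L held 18.7% of conservative and 17.4% of candidate summits (odds ratio 1.09, exact adjusted p = 0.0239). Arm 3L held 21.5% and 19.9% (odds ratio 1.10, exact adjusted p = 0.0103), a call lost against random positions (exact adjusted p = 0.0512) and among the strongest peaks (exact adjusted p = 0.0676). Arm 3R held 23.1% and 24.5% (odds ratio 0.925, exact adjusted p = 0.0239), which was lost against random positions (exact adjusted p = 0.725). It was also lost (24.0% and 24.5%, exact adjusted p = 0.404) when 134 peaks past the authors' threshold that the conservative list leaves out, 84 of them on 3R, were counted as peaks, a choice made after seeing the data. The X chromosome held 18.2% and 19.4% (odds ratio 0.925, exact adjusted p = 0.0348), which was lost without replicate 1 (exact adjusted p = 0.0714) and among the strongest peaks (exact adjusted p = 0.276), and turned to 1.07 against random positions. The small chromosome 4 held 13 summits (odds ratio 1.93, exact adjusted p = 0.0362), a call that was lost in the other series-level list (exact adjusted p = 0.102) and turned to the opposite direction against random positions (odds ratio 0.233). Its odds ratio against candidates was 2.32 in the own list of replicate 1 (10 summits) and 3.27 in that of replicate 2 (16 summits). No conservative summit lay on the Y, which held 243 candidates. Soft-masked repeats held 21.2% of conservative and 12.2% of candidate summits (odds ratio 1.93, exact p = 9.01e-78), but against random positions, with 20.8%, the difference did not pass the test (exact p = 0.454).

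Among the gene lists, that of cytoplasmic ribosomal protein genes most often had a promoter peak. Whether peaks at these genes depend on the tagged protein was not tested, because no control library was analysed here. Of 93 such genes, 71 (76.3%, interval 66.8 to 83.8%) had a promoter peak, against 16.7% of the other genes (odds ratio 16.1, exact adjusted p = 2.85e-35, Fisher's exact test). RpL7 had a pooled signal of 599, RpS27 523, RpL14 444 and RpL24 391, with summits at most 43 bp from a start site. Genes for architectural and insulator proteins had a peak in 11 of 18 cases (61.1%, exact adjusted p = 0.000151). Chro, Cp190 (427), which encodes a cofactor of insulator complexes, Trl (289), which encodes GAGA factor, and Dref (236), which encodes a promoter-binding factor, were its highest members. The general transcription machinery had 11 of 21 genes with a peak (52.4%, exact adjusted p = 0.00071). Among them were Nelf-E and TH1, which encode pausing factor subunits, with 444 and 379, and TfIIA-L and Taf5 with 278 and 277. The peak at Nelf-E was the same one as at RpL14, and that at Dref the same one as at RpL13, a gene named after its values were seen.

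The Notch pathway and E(spl) complex list had a peak at 11 of 20 genes (55.0%, exact adjusted p = 0.000444), a call that was lost with a promoter window of 250 bp (exact adjusted p = 0.501). The Notch regulator gene numb had 318, and E(spl)m2-BFM, E(spl)m7-HLH and E(spl)mdelta-HLH had between 173.6 and 187. Another 5 lists passed the test and lost it under several alternatives. Mitochondrial ribosomal protein genes had a peak in 21 of 73 cases (28.8%, exact adjusted p = 0.0286), EGFR and FGF pathway genes in 7 of 16 (exact adjusted p = 0.0286) and Wnt and Hedgehog pathway genes in 7 of 17 (exact adjusted p = 0.0347). Dorsal-ventral patterning genes had one in 8 of 22 (exact adjusted p = 0.0466, turning to an odds ratio of 0.924 among the strongest peaks), and common reference genes in 7 of 15 (exact adjusted p = 0.0214). Against protein-coding genes only, a background chosen after seeing the data, these 5 had adjusted p-values from 0.0808 to 0.202. Examples were mRpS23 (1444, the peak shared with CenG1A), mRpL23 (1104), spi (210), sgg (487), the heart gene tin (589) and Gapdh2 (862).

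None of the 111 replication-dependent histone genes had a promoter peak (exact adjusted p = 1.6e-08). That call ended among genes with any candidate or thresholded summit (exact adjusted p = 1). The remaining 16 lists did not pass the test. Peaks past the threshold that the conservative list leaves out were not counted in any list. Heat shock genes had a peak in 3 of 15 cases (exact adjusted p = 0.835), with Hsp27 at 563, Hsp83 at 435 and Hsp26 at 281. Polycomb and Trithorax group genes had one in 7 of 20 (exact adjusted p = 0.116), with ph-p, brm at 670 and E(z) at 329. Cell cycle and replication genes had one in 10 of 34 (exact adjusted p = 0.116), with RnrS at 284. Glial genes had 4 of 10 (exact adjusted p = 0.125), with moody at 611, and neuronal genes 2 of 20 (exact adjusted p = 0.72), with elav at 538. Muscle and mesoderm genes had 6 of 21 (exact adjusted p = 0.232), with sls at 310, and spliceosome genes 6 of 20 (exact adjusted p = 0.214), with U2af50 at 321. ZAD zinc finger genes had 5 of 18 (exact adjusted p = 0.31), epidermal and tracheal genes 4 of 15 (exact adjusted p = 0.423), and oxidative phosphorylation genes 16 of 85 (exact adjusted p = 0.787). The highest of the ZAD genes was the tagged gene CG17328 itself, at 209. Proteasome genes had 6 of 48 (exact adjusted p = 0.72), with Rpn3 at 269, and Hox genes 2 of 8 (exact adjusted p = 0.776), with Dfd at 122. Segmentation genes had 5 of 27 (exact adjusted p = 0.851), with nkd at 413, and germline genes 5 of 26 (exact adjusted p = 0.851), with cuff at 228. Neuroblast genes had 3 of 19 and gut, fat body and blood genes 2 of 15 (both exact adjusted p = 1).

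**Figure D3:**
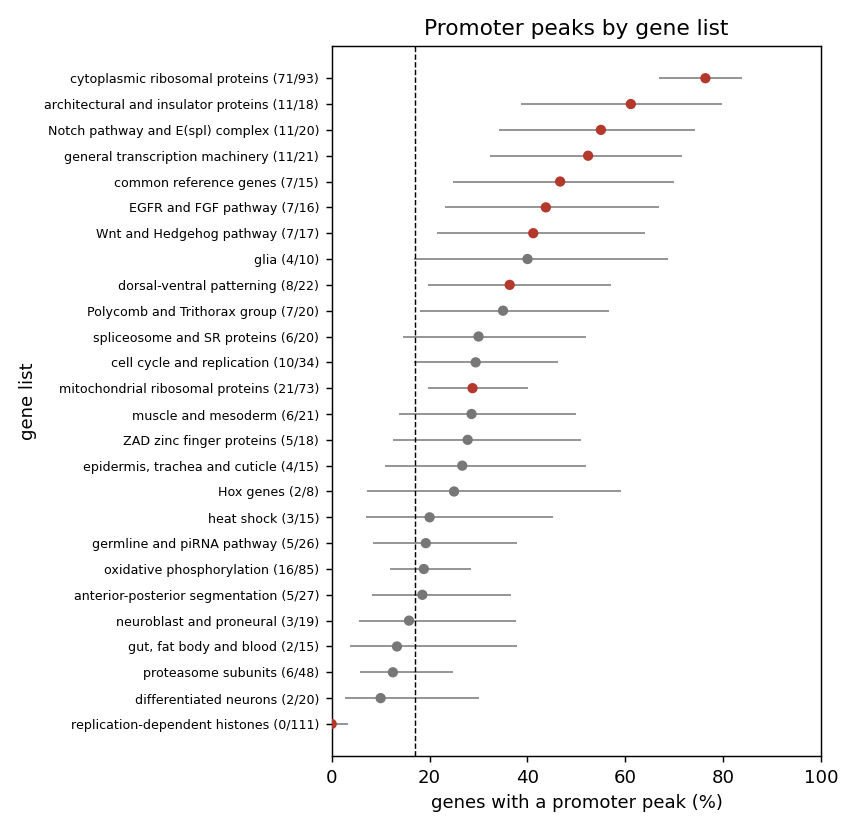
Percent of genes with a conservative summit within 500 bp of a start site (x axis) for each of 26 gene lists (y axis, with counts), with Wilson 95% intervals; red points passed an adjusted p of 0.05 and the dashed line marks all genes at 17.0%. Cytoplasmic ribosomal proteins lie at 76.3% and replication-dependent histones at 0.

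By gene class, protein-coding genes had a promoter peak in 2812 of 13968 cases (20.1%), against 6.82% of all other genes (exact adjusted p = 1.12e-105). The ncRNA class had one in 6.93% (exact adjusted p = 8.86e-75), tRNA genes in 8.28% (exact adjusted p = 0.000135), snoRNA genes in 8.55% (exact adjusted p = 0.000316) and rRNA genes in 0 of 99 (exact adjusted p = 1.12e-07). The snoRNA call turned to an odds ratio of 1.20 with a promoter window of 1000 bp (exact adjusted p = 0.320). snRNA genes were higher, with 11 of 32 (34.4%, exact adjusted p = 0.0347). That call was lost under 5 alternatives (exact adjusted p from 0.0725 to 0.162), and the rRNA call ended among genes with any candidate or thresholded summit (exact adjusted p = 1).

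Sequence at the summits was poor in G+C, a comparison added after the data were seen. Within 50 bp of conservative summits the mean G+C content was 35.8%, against 43.5% in the flanks, a mean difference of -7.71 percentage points (SD 14.4 over 5802 peaks). In the 1450 strongest peaks the difference was -13.5 points and in the 1450 weakest -0.594 points (95% interval -1.34 to 0.148). Candidate summits were instead richer than their flanks, by 3.75 points. The difference was -7.89 points in the list of replicate 1 and -10.8 points in that of replicate 2. In the strongest peak of all, the 41 bp around the summit held 46.3% G+C (2R from 22678387 to 22678427). The summit of CG14100, with 29.3%, lay in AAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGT (3L from 19590595 to 19590635), and that of ph-p, with 24.4%, in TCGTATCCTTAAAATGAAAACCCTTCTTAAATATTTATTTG (X from 2137328 to 2137368).

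**Figure D4:**
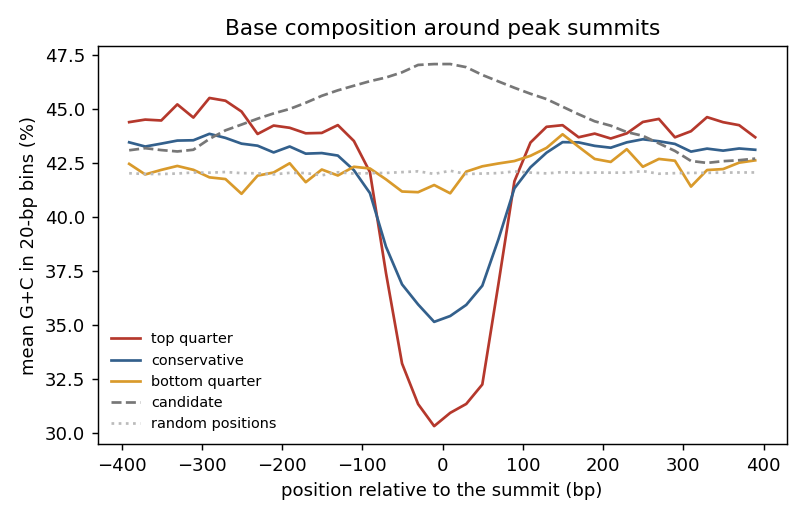
Mean G+C content in percent (y axis) by position relative to the summit in bp (x axis) for the 1450 strongest, all 5802 and the 1450 weakest conservative peaks, candidate peaks and random positions. The strongest peaks average 31.1% within 50 bp of the summit and candidates 47.0%.

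Of the fixed words, that of the insulator protein CTCF stood highest. It was present at 1.48% of summits and 0.172% of flanks (8.60-fold, exact adjusted p = 4.5e-15, exact sign test). The DRE word of DREF was at 1.15% against 0.396% (2.91-fold, exact adjusted p = 1.18e-05), and core promoter motif 7 at 2.43% against 1.26% (1.93-fold, exact adjusted p = 1.09e-05). In all, 12 of 28 words were more frequent at summits and 7 less frequent. The counts were 13 and 4 without replicate 2, 9 and 4 with a window of 25 bp on each side, and 9 and 3 against the candidates of equal G+C content described next. Against candidates of equal G+C content, a background chosen after seeing the data, CTCF (12.6-fold), DRE (2.72-fold) and motif 7 (2.07-fold) stayed higher. The control word of C and G alone was also higher there (2.29-fold, exact adjusted p = 5.86e-06), by more than motif 7 and GAGA factor, although it did not pass against flanks (0.917-fold, exact adjusted p = 0.759). The Hunchback word (1.65-fold against flanks, exact adjusted p = 2.33e-16) and the homeodomain word (1.51-fold, exact adjusted p = 2.9e-09) did not, at 0.928-fold and 0.914-fold. The GAGA factor word was lower than in flanks (0.388-fold, exact adjusted p = 8.57e-12) but higher than in the matched candidates (1.46-fold, exact adjusted p = 0.0154).

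**Figure D5:**
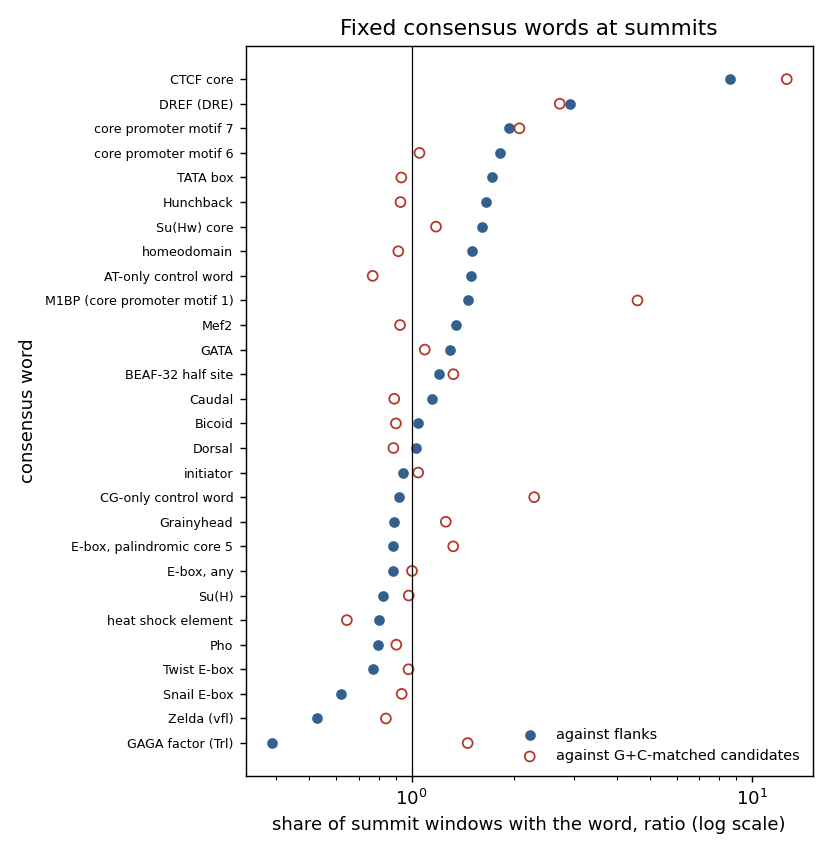
Ratio of the share of summit windows with each of 28 consensus words (y axis) to the share in flanks (filled) or in candidate summits of equal G+C content (open), on a log axis; the line marks a ratio of 1. The CTCF word lies at 8.60 and 12.6.

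The leading 8-letter word was TATTTTAA, which holds no G or C. On the held-out arms it was at 181 of 3644 summits (4.97%) and 68 flanks (1.87%), a 2.66-fold difference (exact p = 2.47e-13, exact sign test). Against candidates of equal G+C content the ratio was 1.42 (exact p = 5e-05, Fisher's exact test). The word was more frequent among the 1450 strongest than the 1450 weakest conservative peaks, at 7.59% against 2.69% (exact p = 2.01e-09), and so were promoters, at 50% against 40.6% (exact p = 3.83e-07). These shares include the arms on which the word was chosen. Mean G+C within 50 bp of the summit was 31.1% in the strongest and 41.5% in the weakest peaks. A fixed control word of A and T alone also rose, at 52 against 26 summits (odds ratio 2.04, and 2.97 for TATTTTAA). The split was not repeated at equal G+C. Peaks of 1 replicate only, pooled over both replicates (2125), were at promoters in 42.2% of cases. Shared peaks, counted by the replicate 1 peak (2900), were there in 46.1% (exact p = 0.00532, Fisher's exact test). The whole list of replicate 1 stood at 46.5% and that of replicate 2 at 43.7%. The unshared peaks of replicate 1 were therefore no lower than the shared ones, and the lower share came from replicate 2. TATTTTAA was in 4.24% of peaks of 1 replicate only and in 6.14% of shared peaks (exact p = 0.0034, Fisher's exact test). Neither test was made for each replicate on its own.

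At the tagged gene itself, CG17328 (FBgn0028895, 2L from 16299943 to 16301765), 2 conservative summits lay within 5000 bp. The first, from 16299999 to 16300314, had a pooled signal of 209 and rank 900 of 5807, and measured 97.8 in replicate 1 and 117 in replicate 2. The second, from 16301240 to 16301555, had 58.6. The other series-level list held 5 peaks in this region.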

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

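The tests on the A/T-rich centre and on the region of the tagged gene, with or without left-out peaks, were chosen only after the result was seen.

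Some peaks past the authors' threshold were counted as candidate background in the main comparisons. In the series-level ranked list, 137 peaks at an IDR of 0.01 or less are not in the conservative list, and the highest, near cbt on 2L, has a pooled signal of 1610. Of the 134 on chromosome arms, all of which count among the 127960 candidates, 84 lie on 3R. They form 60 runs of neighbouring peaks, against a mean of 131 and a lowest of 126 in 1000 random draws of the same number. The left-out peaks thus lie in stretches, and none overlaps a thresholded peak of either sample. The gene-list counts leave them out too, and the list tests were not rerun with them. Among them are promoter summits at RpL13A (-49 bp, signal 304), Hsp70Ba (-71 bp, 92.2) and TfIIA-S (-79 bp, 83.1). The own lists of the samples also leave out ranked peaks past the threshold. Of those on the arms, 63.3% lie on 3R in replicate 1 and 63.0% in replicate 2. The reason is not given in the sources used here. If whole stretches were left out, other candidates and genes there could not be called either. Such candidates and genes would still count as background or as genes without a peak, and no test was run without the stretches.

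The A/T-rich centre of the conservative peaks was set against technical explanations. If A/T-rich fragments were over-represented wherever they occur, places with such a dip should hold more ranked peaks than other places. Of 298042 genomic windows with a dip as deep as the mean of the strongest peaks, 14.0% lie within 100 bp of a ranked summit. The share of all windows was 19.9% (ratio 0.702, bootstrap interval 0.680 to 0.724 over blocks of 1000000 bp), counting ranked summits whether thresholded or not. Most ranked summits were candidates, whose centres are richer in G+C than their flanks, so a ratio below 1 could be foreseen. The ranked lists also had a control alignment as input, and no read coverage was available, so this explanation stays open. Promoter composition is argued against by the peaks away from promoters, which dip by -9.24 points. A preference of the protein for such sequence was not tested, nor any other biological explanation.

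The strongest peak, on 2R, is 7.12 times the next. Near-identical copies in the reference are argued against, since its sequence has 0 further matches of at least 90% identity over 50% of its length. Copies that the reference itself lacks stay open. Extra copies of the region would raise the signal around the peak. The candidate peaks within 20000 bp have a median signal of 26.2, at percentile 99.7 of 1000 random places, as extra copies would predict. This value cannot tell extra copies from binding nearby, and it is far below the excess of the peak itself. No biological explanation was tested.

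At the tagged gene, an inserted copy could raise the signal of the whole region. The median candidate signal within 20000 bp of CG17328 was 20.6, at percentile 87.3 of 1000 random places, and 4 conservative peaks lay there, a number that 188 of the 1000 places reached. With the left-out peaks past the threshold counted as peaks, the number was 8, which 32 of the 1000 places reached; the 4 added peaks, near crp, have signals from 75.0 to 262. The length of any inserted segment is not known here, so extra copies and binding cannot be told apart for this region. No biological explanation was tested.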

How the results depend on the processing

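Backgrounds of equal G+C content, of protein-coding genes and of strong candidates, and counting left-out peaks as peaks, were chosen after seeing the data. Of 64 alternative values of the main results, 53 kept direction and side of the threshold, or stayed within 1.5 times or the spread. For the others the cause was not tested unless named. The peak count was 2901 among the strongest peaks, by construction, and 3713 to 4216 without a replicate. With summits within 100 bp rho was 0.836. Against random positions the masked-repeat odds ratio was 1.03 and 3 arms were called; the odds ratios were 0.907 for introns, 0.233 for chromosome 4 and 1.07 for X, each in the opposite direction. The 9 lists called higher became 5 to 7 without a replicate, 4 among genes with a summit and 4 among protein-coding genes. Dorsal-ventral patterning turned to 0.924 among the strongest peaks, and snoRNA genes to 1.20 with a 1000 bp window. The tagged locus held 5 peaks in the other series-level list, 1 among the strongest peaks and 3 to 4 without a replicate. Words less frequent at summits fell from 7 to between 3 and 4 without replicate 2, with a 25 bp window and at equal G+C. The Dorsal word turned to 0.614 against candidate summits. Against candidates of equal G+C, ratios turned for GAGA factor (1.46), the TATA box (0.933), any E-box (1.00), the palindromic E-box (1.32), homeodomain (0.914), Hunchback (0.928), Caudal (0.889), the CG-only word (2.29) and the A/T-only word (0.768). Calls on cytoplasmic ribosomal, architectural and general transcription genes held under every alternative run. No paired analysis was possible because there is only 1 group. Unknown read depth limits what a missing peak can show.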

Other observations

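The tests in this part were chosen after the result was seen. Some of the promoter words separated by location, and so did a control word. Only conservative peaks were compared, without promoters that lack such a peak. The split therefore cannot tell sites of the protein from promoters in general. The DRE word was 16.8 times as likely, by odds, in conservative promoter peaks as in those away from promoters (exact adjusted p = 1.22e-16, Fisher's exact test over 28 words). For the M1BP word the odds ratio was 11.3 (exact adjusted p = 2.77e-10) and for core promoter motif 7 it was 3.69 (exact adjusted p = 3.37e-12). The control word of C and G alone lay above motif 7, at 6.04 (exact adjusted p = 2.26e-08). Core promoter motif 6 (1.09, exact adjusted p = 0.667), the TATA box (1.09, exact adjusted p = 0.730) and the initiator (1.13, exact adjusted p = 0.316) did not pass the test. The CTCF word did not differ detectably (odds ratio 0.742, exact adjusted p = 0.316).

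By strength, the CTCF word was at 16 of the 1450 strongest and 17 of the 1450 weakest conservative summits. The GAGA factor word was at 7 and 28 (exact adjusted p = 0.00147), and so was the control word of C and G alone, with the same p. The Hunchback word was at 14.7% and 7.86% (odds ratio 2.02, exact adjusted p = 1.95e-07), and the control word of A and T alone at 52 and 26 summits (odds ratio 2.04, exact adjusted p = 0.00976). These differences by strength are no larger than those of the control words.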
